A study of Mus musculus with 16 samples.

How the data were processed

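Single-cell 3' expression libraries of mouse CD8+ T cells were analysed: 8 libraries of endogenous T cells from MC38-OVA or B16-OVA tumors and 8 libraries of transferred OT-I cells from tumor-draining lymph nodes. In each tissue the 8 libraries were the combinations of 2 tumor models, 2 genotypes and 2 treatments, with 1 library of pooled mice each. The deposited files hold UMI counts per gene and barcode, which the authors made with Cell Ranger 3.1.0 per the file headers, against mm10 per the submitters' processing notes. The count matrices list cell-called barcodes, and no further normalization or filter by the authors was found in them. Each matrix has 31053 Ensembl genes and 1 added vector feature, EGFP, whose origin is not given in the sources used here. Of the Ensembl identifiers 31011 (99.86%) were found in GENCODE release 21 for mouse (GRCm38, the assembly of mm10), from which positions were taken.

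Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept, and doublets called by Scrublet (in scanpy 1.11.5, expected rate 6%) were removed. Scrublet called 0 cells in all 8 tumor libraries and in 3 lymph node libraries of MC38, so that this step removed nothing there. For that reason the 6% of cells of each library with the highest doublet score were also removed as an alternative. Cells of each tissue and tumor model were normalised to 10000 UMIs, reduced to 2000 variable genes (without Tcf7, T cell receptor and immunoglobulin segments, Xist and Y-linked genes) and 30 principal components, and clustered with 15 neighbours by the Leiden method (leidenalg 0.10.2, igraph 0.11.9, resolution 0.6, seed 0). A cluster was named from fixed marker lists when its top 20 genes by fold over the other cells (at least 50 CPM in the cluster) held 3 markers of a class, with 1 or more among the leading 5. Clusters named as myeloid, B, NK or tumor and stroma cells were removed, and all others were kept in the sums, named or not, and are called T cells below. By that rule 4 small unnamed clusters that may hold other cells stayed in: 56 cells of B16 tumors led by Ly6d and Siglech (Cd3e at 133.7 CPM), 23 cells of B16 lymph nodes with Il4i1 and Cacnb3 among their leading genes (Cd8a at 116.4 CPM), 56 cells of B16 lymph nodes led by Tcrg-C4, with Trdc among their leading genes (Cd8a at 221.4 CPM), and 167 cells of MC38 tumors led by Foxp3, with Cd4 among their leading genes. Sums without them were not made. Removed clusters may in turn hold some T cells. In B16 tumors Cd8a was at 445.7 CPM in the larger removed myeloid-like cluster and 359.9 CPM in the removed NK-like cluster. It was at 348.7 CPM in the kept naive/central-memory-like cluster. A rule that keeps clusters led by heat shock genes unnamed, and the omission of haemoglobin genes from the ranking, were set after the clusters were seen. The rule left unnamed a lymph node cluster of B16 led by Hspa1b and Hspa1a, with 43.5% of WT isotype, 48.4% of KO isotype, 25.4% of WT ICB and 3.46% of KO ICB cells.

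UMI counts were summed over the T cells of each library. The sums were 6316625 to 98392229 UMIs, so that counting error is small for genes above 20 CPM, and the limit of a count of 0 was set at 3 counts per library. Exact Poisson 95% intervals are given for CPM and Wilson 95% intervals for shares of cells. Both cover counting error only. Effects were tested in each tissue with edgeR 4.0.16 (filterByExpr, TMM scaling, glmQLFit with robust set, glmQLFTest) over all 8 libraries, with the combinations of the other 2 factors as blocks. Interactions, and genotype effects within a tumor model, were fitted as contrasts over the same 8 libraries. P-values were adjusted by Benjamini and Hochberg over all genes tested in a comparison at a threshold of 0.05, in 14 tested comparisons. Standard errors were taken as the size of the log2 fold change divided by the root of the F statistic. The test was run on simulated data of the same size and depth with known changes of 1 or 2 log2. It also called unchanged genes, from 6 to 23 per comparison. In tumor genotype by treatment 23 unchanged genes were called beside 52 and 77 genes changed by 1 and 2 log2. In lymph node genotype in MC38 there were 23 beside 68 and 95. In tumor treatment there were 17 beside 79 and 98, and in lymph node genotype 16 beside 91 and 98. The share of false calls thus exceeded the threshold of 0.05 in these comparisons. Of all simulated comparisons only lymph node treatment lay under it, with 9 beside 89 and 97. Gene lists were tested with camera on voom values (limma 3.58.1) with a preset correlation of 0.01 and with a correlation estimated per list, adjusted over the lists of a comparison. With an estimated correlation camera also uses only the residual degrees of freedom of the fit, 2 or 3 here. A call lost there thus cannot be laid to correlation between genes alone. There were 22 fixed lists: naive and memory genes, cytotoxic genes, effector differentiation, NK receptors, checkpoint and exhaustion, cytokines and chemokines, early TCR response, type I interferon, cell cycle, homing and residency, costimulation and cytokine receptors, glycolysis and hypoxia, oxidative phosphorylation, Myc and ribosome biogenesis, antigen presentation, heat shock and dissociation, core TCR signalling, and markers of myeloid, B, CD4 or regulatory or gamma-delta T or NK, tumor and stroma, and erythroid cells. Ribosomal protein and mitochondrial genes were tested beside them. The 16 comparisons of 2 single libraries had no test. Their list medians were also set against 10000 random lists matched on expression, which carry no spread between libraries and treat genes as independent, so that these percentiles are not given.

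Genes named in the text were chosen by rule: Tcf7, Pdcd1, Havcr2 and Cd274 in every comparison, the 6 largest rises and the 6 largest falls among genes that passed, went the same way in every pair and had a mean of at least 20 CPM, and 2 members that passed per fixed list. In single-library comparisons the rule took the 5 largest rises and falls of at least 1 log2 with at least 100 UMIs and 20 CPM, and 2 members per list. T cell receptor and immunoglobulin segments, Xist, Y-linked, mitochondrial and ribosomal protein genes, haemoglobins, unnamed gene models and markers of other cells were left out of the largest changes. Genes named outside the rule are given as chosen after their values were seen.

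The groups, comparisons, tests, lists and naming rule of genes were fixed before the data were examined, as were these alternatives: DESeq2 1.42.0 (size factors, and its Wald test), no filter on low counts, an additive model, all barcodes, cells with a Cd8a or Cd8b1 UMI, each library left out in turn, another seed, a Leiden resolution of 1.2, doublets kept, at least 1000 genes per cell, and 5 in place of 0.5 counts added. Alternatives chosen after the data were seen were the removal of cells by doublet score, sums within named classes, sums without the lymph node clusters with Ccl5 among their 20 leading genes, clustering without the genes called between ICB and isotype tumors, and treatment effects per tumor model. Sums over all barcodes and over cells with a Cd8a or Cd8b1 UMI include the clusters of other cells removed elsewhere. When a library was left out, its partner in the block added nothing to the effect, so that in effect the pair was left out. T cell receptor sequences and protein data were not analysed here. Work was done in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-image 0.26.0, matplotlib 3.10.9) and R 4.3.3.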

Results

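Gene expression was measured in single mouse CD8+ T cells by droplet-based 3' sequencing with molecular barcodes (UMIs), in 16 libraries that each pooled cells of several mice. The mice carried MC38-OVA, a colon carcinoma line, or B16-OVA, a melanoma line, both expressing ovalbumin. They received antibodies against PD-L1 and Tim-3 (200 µg of each, checkpoint blockade, here ICB) or isotype control antibodies. CD8+ T cells were wild type (WT, floxed Tcf7 without Cre) or labelled as knockout (KO, floxed Tcf7 with the CD8 lineage Cre E8i). Tcf7 encodes the transcription factor TCF1. In 8 libraries the cells were endogenous T cells sorted from tumors of 3 to 5 mice, dosed on days 6 and 9 and taken 2 days (MC38) or 3 days (B16) after the second dose. In the other 8 libraries they were OT-I T cells, which carry a receptor for an ovalbumin peptide, transferred on day 5 into mice with congenic CD45.1 cells and sorted from the tumor-draining lymph node on day 8, after 1 dose on day 6. Each combination of tissue, tumor model, genotype and treatment had 1 library, so that 16 groups held 1 library each.

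The matrices held 105896 barcodes, of which 84701 passed as T cells. A tumor library held 5033 to 9105 T cells and 47013135 to 98392229 UMIs in them. The lymph node libraries of the MC38 experiment held 1164 to 8230 T cells and those of the B16 experiment 786 to 2260, with 6316625 UMIs in the smallest (B16 WT isotype). Between 78.7% and 91.1% of barcodes passed the quality limits in the tumor and MC38 lymph node libraries, and 52.7% to 71.0% in the B16 lymph node libraries. The tumor model was confounded with the experiment in both tissues and, in tumors, with the day of harvest. Errors given with log2 fold changes are standard errors of the edgeR fit over 8 libraries, and intervals given with shares or with UMI counts scaled to the library's total (CPM) are 95% intervals that cover counting error only. P-values measured the spread between pooled libraries in different conditions, since no condition was repeated.

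The targeted gene was examined first. Tcf7 (ENSMUSG00000000782; GRCm38 chromosome 11, 52252371 to 52283014, minus strand) had 70.9 CPM in the WT and 59.9 CPM in the KO isotype library of MC38 tumors, and 27.6 and 33.5 CPM in the 2 ICB libraries. In B16 tumors the WT and KO libraries had 114 and 65.8 CPM under isotype and 40.9 and 42.1 CPM under ICB. In the lymph node the WT and KO values were 329 and 399 CPM (MC38 isotype), 292 and 516 CPM (MC38 ICB), 274 and 262 CPM (B16 isotype) and 273 and 357 CPM (B16 ICB). The KO effect on Tcf7 was -0.16 ± 0.15 log2 in tumors (adjusted p = 0.797) and 0.30 ± 0.13 log2 in the lymph node (adjusted p = 0.289, edgeR). Thus the Tcf7 count did not separate the genotypes, and in the lymph node it went against the KO label in 3 of 4 pairs. The 3' tags counted by this assay can lie outside the deleted part of the gene and then check nothing, and the matrices do not give their position. A vector sequence in the reference, EGFP, had 12 to 64 UMIs in each of the 8 libraries labelled KO and 0 in each of the 8 WT libraries (263 UMIs in 452540139 against 0 in 489419333). Below, KO stands for the libraries labelled KO, and every direction between genotypes rests on that label.

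The first question was which T cell states the tumors held. Cells of each tissue and tumor model were clustered separately, and clusters were named only from fixed markers. Under ICB, a larger share of the T cells fell into the exhausted-like class, led by the granzyme genes Gzmd, Gzmf and Gzmc in both models, in WT cells of both tumor models and in KO cells of B16, but not in KO cells of MC38. In MC38 the class rested on granzyme genes and Prf1, with no inhibitory receptor gene among the 20 leading genes of its cluster, while in B16 Havcr2 and Lag3 were among them. The largest MC38 cluster (6409 cells), with Lag3 among its 20 leading genes, stayed unnamed and was not counted in the class. In MC38 tumors the exhausted-like share was 11.5% (10.7 to 12.4, Wilson) in the WT isotype and 25.8% (24.9 to 26.8) in the WT ICB library, against 12.5% (11.8 to 13.2) and 9.53% (8.76 to 10.3) in the KO libraries. In B16 tumors it was 8.87% (8.26 to 9.51) and 32.6% (31.5 to 33.7) in WT, and 17.6% (16.8 to 18.4) and 23.6% (22.6 to 24.5) in KO. Gzmd was far lower in the KO than in the WT isotype library of B16 (values below), although the class share was higher there. The class thus need not rest on the same genes in every library. With the 222 genes that differed between ICB and isotype tumors left out of the clustering, the shares were 12.7% and 27.5% (MC38 WT), 13.3% and 10.8% (MC38 KO), 9.04% and 31.8% (B16 WT) and 17.8% and 23.4% (B16 KO). At the finer clustering resolution the share was higher with ICB in all 4 pairs.

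The proliferating class, named by cell cycle and histone genes, held 5.19% and 14.6% of WT cells in MC38 tumors (isotype and ICB) and 7.95% and 8.23% of KO cells, where the intervals overlapped. In B16 tumors it held 10.8% and 27.2% of WT cells and 24.7% and 26.7% of KO cells, so that the KO isotype library already lay near the level of the ICB libraries. The naive/central-memory-like class was smaller with ICB in 4 of 4 pairs and under every setting. Its share was 12.8% and 7.96% (MC38 WT), 16.7% and 5.21% (MC38 KO), 20.1% and 6.43% (B16 WT) and 23.0% and 11.0% (B16 KO). In MC38 it comprised a cluster led by the NK receptor gene Klra7, and a smaller one led by Dapl1. The Klra7 cluster held most of the class in 3 libraries, while in the WT ICB library the Dapl1 cluster held 4.30% and the other 3.66% of T cells. A progenitor-exhausted-like class led by Xcl1, Ccl1, Penk, Dapl1 and Crtam was named in B16 alone, with 10.7% and 8.80% of WT and 5.21% and 5.99% of KO cells. An interferon-response-like class held 20.7% (19.6 to 21.8) of the KO ICB cells in MC38 and 2.77% to 9.17% elsewhere, but its direction with ICB changed with the seed, the resolution of the clustering and the removal of cells with high doublet scores. No test was made on these shares. Over 4 pairs the smallest p of an exact two-sided sign-flip test is 2 in 16, which is above 0.05. The intervals cover counting error, and 48 of 78 class shares of both tissues left theirs at the finer clustering resolution and 24 of 74 with another seed. The unnamed clusters held 42.4% to 65.6% of T cells in MC38 and 21.97% to 46.7% in B16. The sort for CD8 and the minimum of 500 genes also act on these shares, since the median UMI count of proliferating cells in MC38 was 15990.5 and that of the Dapl1 cluster 3195. Myeloid-like clusters, removed before all sums, held 5.02% to 8.49% of the cells in B16 and 0.543% to 1.22% in MC38.

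**Figure D1:**
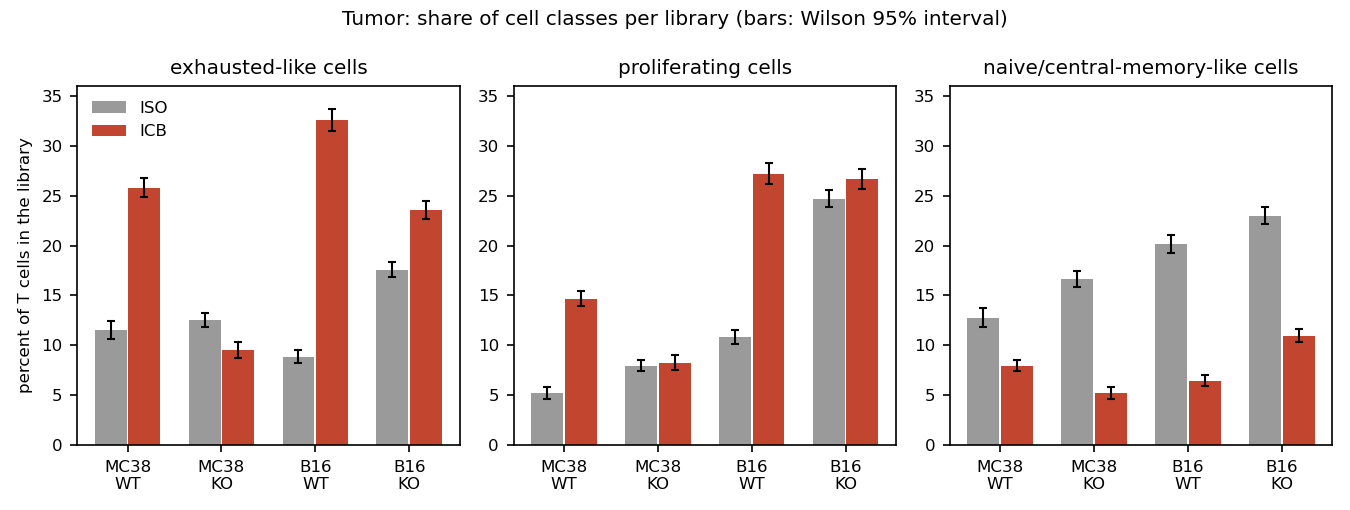
Share of T cells (percent, vertical axis) in the exhausted-like, proliferating and naive/central-memory-like classes of the 8 tumor libraries, with 1 bar per library and Wilson 95% intervals as error bars. The exhausted-like share was 25.8% and 32.6% in the WT ICB libraries of MC38 and B16 and 9.53% and 23.6% in the KO ICB libraries.

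The second comparison asked how ICB changed expression in tumor T cells, over 4 pairs of ICB and isotype libraries (2 tumor models and 2 genotypes). Of the lists fixed beforehand, 3 of 16 cytotoxic and 5 of 17 checkpoint and exhaustion genes rose with ICB and 5 of 20 naive and memory genes fell, while no list call held with an estimated correlation between genes. Prf1, which encodes perforin (ENSMUSG00000037202; chromosome 10, 61297833 to 61304680), rose by 1.18 ± 0.15 log2 (adjusted p = 0.0283), from 540 to 1062 CPM in MC38 WT and from 298 to 841 CPM in B16 WT cells. Havcr2, which encodes Tim-3, one of the antibody targets (ENSMUSG00000020399; chromosome 11, 46454935 to 46481255), rose by 0.75 ± 0.09 log2 (adjusted p = 0.0156), from 134 to 221 CPM in MC38 WT and from 79.0 to 139 CPM in B16 WT cells. Bcl2, an inhibitor of apoptosis (ENSMUSG00000057329; chromosome 1, 106538178 to 106714274), fell by 1.12 ± 0.16 log2 (adjusted p = 0.0347). Tcf7 itself fell by 1.04 ± 0.14 log2 (adjusted p = 0.0302). Of the 29 genes that passed here and were named by rule, 26 lost their call over all barcodes and 27 over cells with a Cd8a or Cd8b1 UMI. Both settings bring back the clusters of other cells removed from the T cell sums. Whether that explains the lost calls was not tested.

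Of 13433 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 109 rose and 113 fell with ICB, and 109 and 112 of these went the same way in all 4 pairs. The largest rises under the fixed rule were Serpine2, a protease inhibitor (1.45 ± 0.21), Rgs2, a regulator of G protein signalling (1.22 ± 0.13), Prf1, the metallothioneins Mt2 (1.18 ± 0.08) and Mt1 (1.08 ± 0.09) and the sulfotransferase Sult2b1 (1.08 ± 0.08). The large falls under the same rule included, besides Bcl2 and Tcf7, Klf3, a zinc finger transcription factor (-1.34 ± 0.18), the lectin gene Clec2i (-1.22 ± 0.16) and Pdlim1 (-0.82 ± 0.11). Of the other genes fixed for every comparison, Pdcd1 (PD-1) was at 0.49 ± 0.11 log2 and did not pass (adjusted p = 0.0855), and Cd274 (PD-L1) was at -0.03 ± 0.09 log2 (adjusted p = 0.909).

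Of the 20 members of the naive and memory list, 5 fell and 0 rose, among them Igfbp4 (-1.82 ± 0.19) and Tnfsf8 (-1.50 ± 0.12), and 11 fell and 1 rose adjusted over the list alone (camera adjusted p = 6.36e-11, and adjusted p = 0.446 with an estimated correlation). Of 17 checkpoint and exhaustion genes, 5 rose and 0 fell, including Tox2 (1.33 ± 0.16) and Havcr2, and 12 rose adjusted over the list alone (3.55e-08 by camera, adjusted p = 0.446 with an estimated correlation). Of 16 cytotoxic genes, 3 rose, including Prf1 and the granzyme B inhibitor Serpinb9 (0.77 ± 0.10), and 5 rose and 1 fell adjusted over the list alone (0.000605 by camera, adjusted p = 0.446 with an estimated correlation). Of 18 cytokine and chemokine genes, 4 rose and 1 fell (6 and 4 adjusted over the list alone). They included Areg, an epidermal growth factor receptor ligand, at 3.07 ± 0.44, and Il10 at 1.72 ± 0.28, and camera called no direction (adjusted p = 0.218). Of 17 homing and residency genes 4 rose, including Rgs2 and Ly6a (0.68 ± 0.08), and 5 rose and 3 fell adjusted over the list alone. The median of that list was -0.16, while its test pointed up (adjusted p = 0.693). Of 20 costimulation and cytokine receptor genes 2 rose, Il12rb1 (0.63 ± 0.09) and Il12rb2 (0.53 ± 0.09), which encode the IL-12 receptor, and 6 rose adjusted over the list alone (0.0033 by camera, adjusted p = 0.446 with an estimated correlation). Of 15 NK receptor genes 1 rose, Klrc2 (0.70 ± 0.10), and 7 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.0862).

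No member of the other lists of T cell programs passed in this comparison. Of 15 effector genes 6 were higher and 1 lower adjusted over the list alone, with a median of 0.13, a mean of -0.04 and a test pointing up (adjusted p = 0.222). Of 16 early TCR response genes 1 was higher and 1 lower adjusted over the list alone (camera adjusted p = 0.722). Of the 20 cell cycle genes 19 had values above 0 with a median of 0.26, and 0 passed adjusted over the list alone (0.0033 by camera, adjusted p = 0.657 with an estimated correlation). The 21 type I interferon genes had a median of -0.20 (0.0164 by camera, adjusted p = 0.470 with an estimated correlation). Camera called none of glycolysis and hypoxia (adjusted p = 0.0816), oxidative phosphorylation (0.0531), Myc and ribosome biogenesis (0.254), antigen presentation (0.400), heat shock (0.238), core TCR signalling (0.0712) or ribosomal proteins (0.118), and it called the 13 mitochondrial genes down (0.0466, adjusted p = 0.543 with an estimated correlation). Adjusted over the list alone, 0 members of these lists passed.

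Members of the lists of markers of other cells also moved with ICB. Of 5 B cell markers, Ighd (-1.42 ± 0.24) and Ighm (-0.56 ± 0.08) fell, and their list had 3 falls adjusted over the list alone (camera adjusted p = 0.00531, and 0.446 with an estimated correlation as adjusted p). The summed CPM of B cell markers was 220 and 69.1 in B16 WT and 74.1 and 129 in B16 KO cells (isotype and ICB), and 43.6 to 74.1 in MC38. Of 10 CD4, regulatory, gamma-delta T and NK cell markers, Tcrg-C1 (-1.24 ± 0.17) and Eomes (-0.52 ± 0.08) fell, and 3 fell adjusted over the list alone (0.0182 by camera, adjusted p = 0.543 with an estimated correlation). Eomes also stood in the naive and memory list. Ighm and Tcrg-C2 were among the 20 leading genes of the Klra7 cluster of MC38, kept as naive/central-memory-like T cells. Falls in these lists thus need not come from other cells. Of 13 tumor and stroma markers, Dct (-0.86 ± 0.14, in 3 of 4 pairs) and Pecam1 (-0.56 ± 0.09) fell, and 4 fell adjusted over the list alone (0.0033 by camera, adjusted p = 0.446 with an estimated correlation). Of 16 myeloid markers 14 lay above 0 and 0 passed (0.0146 by camera, adjusted p = 0.543 with an estimated correlation). The 4 haemoglobin genes tested did not pass (0.028 by camera, adjusted p = 0.589 with an estimated correlation), and their summed CPM was 134 in B16 WT isotype and 1.32 in B16 WT ICB cells. Sums over all barcodes or over cells with a Cd8a or Cd8b1 UMI bring back the clusters of other cells removed here. In the B16 WT isotype tumor library 8216 cells had such a UMI, against 7919 T cells. In every MC38 tumor library such cells were fewer than the T cells (4960 against 5033 in WT isotype). Whether the returned clusters caused the loss of calls was not tested. The count of 222 genes was 835 with DESeq2, 440 without the filter on low counts, 20 over all barcodes and 18 over cells with a Cd8a or Cd8b1 UMI. It was 30 and 31 without the MC38 WT isotype or ICB library, 41 and 45 without the B16 WT isotype or ICB library, and 112 and 79 without the B16 KO isotype or ICB library.

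**Figure D2:**
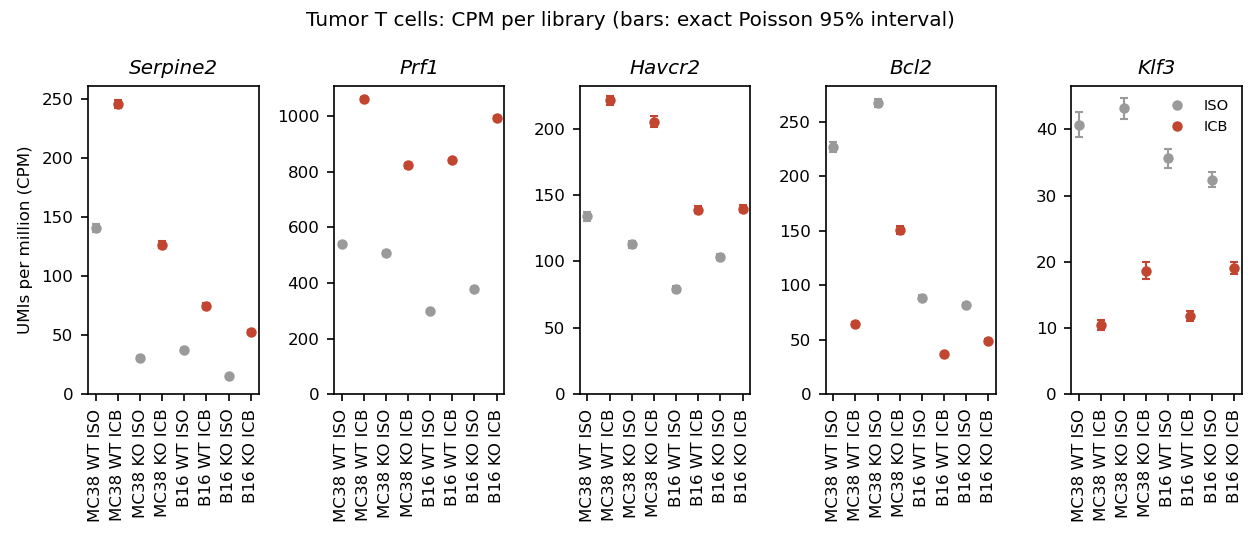
CPM (vertical, linear axes from 0) of Serpine2, Prf1, Havcr2, Bcl2 and Klf3 in the 8 tumor libraries, with 1 point per library (grey isotype, red ICB) and exact Poisson 95% intervals as error bars. Prf1 lay between 298 and 540 CPM in the isotype libraries and between 823 and 1062 CPM in the ICB libraries.

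The third comparison asked how tumor T cells labelled KO differed from WT cells, over 4 pairs of KO and WT libraries. Only 2 of 13433 genes passed, and interferon-stimulated and antigen presentation genes lay above 0 together without single members passing over all T cells. Ppp2r3a, a phosphatase regulatory subunit, fell by 1.45 ± 0.12 log2 (adjusted p = 0.0448, mean 3.58 CPM), and 1700029J03Rik rose (7.22 ± 0.57 log2, adjusted p = 0.0448, mean 0.680 CPM). Both were singled out after their values were seen, since they lie under the expression minimum of the rule. Pdcd1 (0.15 log2, adjusted p = 0.745), Havcr2 (0.03, adjusted p = 0.956) and Cd274 (0.04, adjusted p = 0.918) did not pass. The edgeR test gave 1158 genes at an unadjusted p under 0.05, and DESeq2 called 204 genes. In simulated data of this size and depth the test recovered 74.7% of genes changed by 1 log2 and 97.0% of those changed by 2 log2. Beside these 74 and 96 genes it called 11 unchanged ones.

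All 21 type I interferon genes had values above 0 in KO cells, with a median of 0.50 log2. None passed over all genes tested and 17 rose adjusted over the list alone (1.04e-22 by camera, adjusted p = 0.568 with an estimated correlation). In sums within cell classes, chosen after the data were seen, 5 of these genes rose in the proliferating class, including Ifit1 (0.81 ± 0.09, adjusted p = 0.0041) and Rsad2 (0.97 ± 0.13, adjusted p = 0.0124), and 7 in the naive/central-memory-like class, including Ifit3 (0.61 ± 0.08, adjusted p = 0.000132) and Usp18 (0.53 ± 0.09, adjusted p = 0.00149), all named after their values were seen. In the exhausted-like and interferon-response-like classes 0 passed (edgeR). The median KO minus WT ratio of these genes was 0.19 and 0.94 log2 in MC38 (isotype and ICB) and 0.46 and 0.54 log2 in B16. All 17 antigen presentation genes lay above 0 with a median of 0.17, and none passed in either adjustment (1.76e-07 by camera, adjusted p = 0.590 with an estimated correlation). Camera also called glycolysis and hypoxia (4.39e-06), core TCR signalling (0.0116), costimulation (0.0299), oxidative phosphorylation (0.0351) and homing (0.0459) up, and mitochondrial genes (0.0112) and the naive and memory list (0.0491) down. With an estimated correlation the smallest adjusted p of these lists was 0.568. In the naive and memory list 2 genes rose and 5 fell adjusted over the list alone. The cytotoxic list had a median of 0.15, a mean of -0.25 and no call by camera (adjusted p = 0.175). The haemoglobin genes, of erythroid cells, had a median of 1.64 log2 and did not pass. The count of 2 was 1 with an additive model, 53 without the filter on low counts, 0 over all barcodes, 7 without the MC38 KO ICB library, 0 without any 1 of the B16 libraries and 1 without any 1 of the other MC38 libraries.

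Whether the KO effect depended on the tumor model is the question in the study's title. In tumors, 0 of 14088 genes passed in MC38 (edgeR, 914 at an unadjusted p under 0.05, DESeq2 71 genes), 0 in B16 (725, DESeq2 59 genes) and 0 for the difference between the models (460, DESeq2 18 genes). Within cell classes that difference gave 10 genes in the exhausted-like class, including Ifitm1 (1.57 ± 0.15, adjusted p = 0.000824), 14 in the proliferating class, including Fcer1g (2.01 ± 0.15, adjusted p = 0.000171), and 0 in the naive/central-memory-like (436 at an unadjusted p under 0.05) and interferon-response-like classes (321). Both genes were named after their values were seen. Simulated changes of 1 log2 in MC38 alone were recovered for 63.3% of genes, and 17 unchanged genes were called. With 1 library left out, the MC38 count was 23 to 62 except without the MC38 WT ICB library (0). The B16 count was then 17 to 47 except without the MC38 WT ICB library (1), and the count for the difference was 10 to 19 without any 1 B16 library, 4 without MC38 KO ICB, KO isotype or WT isotype, and 0 without MC38 WT ICB. As a list, the NK receptors had a KO effect that was higher in B16 than in MC38, with a median difference of 0.69 log2 (5.14e-10 by camera, adjusted p = 0.684 with an estimated correlation), and 3 of 15 members passed adjusted over the list alone. Cytotoxic genes (median difference 0.21) and glycolysis genes (0.15) pointed the same way (both 0.00191 by camera, adjusted p = 0.684 and adjusted p = 0.826 with an estimated correlation). Camera also called cell cycle genes up (0.0172), and naive and memory genes (0.0172), tumor and stroma markers (0.0252) and mitochondrial genes (0.0453) down, with a smallest adjusted p of 0.826 with an estimated correlation.

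Whether the response to ICB depended on the genotype label was tested as the difference of the ICB effect between KO and WT tumor libraries. With the preset correlation the cell cycle genes had the smallest p of the lists (camera), which did not hold with an estimated one. All 20 had a lower ICB effect in KO than in WT cells, with a median difference of -0.75 log2, 12 passed adjusted over the list alone and 0 over all genes (1.26e-15 by camera, adjusted p = 0.267 with an estimated correlation). In the single pairs, the median ICB to isotype ratio of these genes was 0.81 (MC38) and 0.21 log2 (B16) in WT cells, and -0.13 and -0.05 log2 in KO cells. Heat shock genes (3.08e-07, adjusted p = 0.289 with an estimated correlation) and oxidative phosphorylation genes (1.48e-05, adjusted p = 0.442 with an estimated correlation) also had a lower ICB effect in KO cells. The naive and memory list had a higher one, with a median difference of 0.33 log2 (0.000762, adjusted p = 0.267 with an estimated correlation). Camera also called cytokines (0.000103), NK receptors (0.000128), homing (0.000229), type I interferon (0.00246), costimulation (0.00447) and effector genes (0.00533) higher, and checkpoint (0.00771) and ribosomal protein genes (0.00928) lower. Markers of other cells moved as well, with a higher ICB effect in KO cells for erythroid (7.83e-06), CD4, regulatory, gamma-delta T and NK (0.000103) and B cell markers (0.00465). With an estimated correlation the smallest adjusted p of these lists was 0.267. Of 14088 genes 1 passed, the interferon-inducible gene Ifi202b (adjusted p = 0.0242, mean 1.27 CPM), singled out after its value was seen. Its fitted change of 20.16 log2 comes from libraries without counts and is no bound. The edgeR test gave 1150 genes at an unadjusted p under 0.05, and DESeq2 called 30. The count of 1 was 327 without B16 WT isotype, 321 without B16 WT ICB, 83 without MC38 WT ICB, 75 without MC38 WT isotype, 2 without MC38 KO ICB and 0 without either KO library of B16.

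The next comparison asked how antigen-specific T cells labelled KO differed from WT cells 3 days after transfer, over 4 pairs of KO and WT lymph node libraries. KO cells carried more transcripts of a chemokine, a death ligand and a tissue homing receptor, and fewer of Slamf6 and Dapl1. Ccl5, a chemokine of effector cells (ENSMUSG00000035042; chromosome 11, 83525778 to 83530518), rose by 3.54 ± 0.29 log2 (adjusted p = 0.0039), from 67.5 to 562 CPM in MC38 isotype and from 12.98 to 350 CPM in B16 isotype cells. Coro2a, a coronin (ENSMUSG00000028337; chromosome 4, 46536937 to 46602202), rose by 3.36 ± 0.17 log2 (adjusted p = 2.06e-05). Fasl, the ligand of the death receptor Fas (ENSMUSG00000000817; chromosome 1, 161780689 to 161788495), had 0.00 to 0.47 CPM in the 4 WT and 11.3 to 21.4 CPM in the 4 KO libraries (5.42 ± 0.47 log2, adjusted p = 0.00507). Slamf6, a surface marker of stem-like T cells (ENSMUSG00000015314; chromosome 1, 171917515 to 171953170), fell by 0.73 ± 0.11 log2 (adjusted p = 0.00725), from 124 to 73.7 CPM in MC38 isotype and from 141 to 75.1 CPM in B16 ICB cells.

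Of 11127 genes tested by edgeR, 182 rose and 102 fell in KO cells, and 179 and 101 of them went the same way in all 4 pairs. The largest rises, besides Ccl5 and Coro2a, were Cxcr6, a receptor that guides T cells into tissues (1.87 ± 0.21), Sh3bp5 (1.55 ± 0.16), Bbc3, which encodes the apoptosis inducer PUMA (1.22 ± 0.21), and Apol7e (1.17 ± 0.17). The largest falls were Psen2, a component of gamma-secretase (-1.28 ± 0.11), Tspan32 (-1.14 ± 0.14), Nsg2 (-1.04 ± 0.12), Mpp1 (-1.02 ± 0.13), Ephx1, an epoxide hydrolase (-0.97 ± 0.12), and Dapl1 (-0.90 ± 0.12). Pdcd1 (-0.65 ± 0.40, adjusted p = 0.516), Havcr2 (0.57 ± 0.29, adjusted p = 0.373) and Cd274 (0.38 ± 0.20, adjusted p = 0.387) did not pass over both models together.

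Of 13 cytotoxic genes 3 rose, including Fasl and Prf1 (0.91 ± 0.10), 12 lay above 0, and 9 rose adjusted over the list alone (3.13e-09 by camera, adjusted p = 0.247 with an estimated correlation). Of 15 homing genes 3 rose, including Cxcr6, and 8 rose and 2 fell adjusted over the list alone (8.6e-05, adjusted p = 0.630 with an estimated correlation). Of 13 effector genes 1 rose, Prdm1, which encodes the effector regulator Blimp-1 (1.62 ± 0.30), and 5 rose adjusted over the list alone (0.000175, adjusted p = 0.247 with an estimated correlation). Of 20 naive and memory genes 3 fell, including Dapl1 and Slamf6, while 4 rose and 4 fell adjusted over the list alone, with a median of 0.15, a mean of -0.01 and no call by camera (adjusted p = 0.896). Of 15 checkpoint genes 2 rose, Maf (1.77 ± 0.17) and Cd101 (0.95 ± 0.14), and 1 fell, with a median of -0.04, a mean of 0.03 and a test pointing up (adjusted p = 0.806). Of 10 cytokine genes 1 rose, Ccl5, and 1 fell, Tnfsf11 (-1.44 ± 0.23), with 5 rises and 3 falls adjusted over the list alone (0.036 by camera, adjusted p = 0.698 with an estimated correlation). Of 20 costimulation and cytokine receptor genes 2 rose, Il2ra, the high-affinity IL-2 receptor chain (2.05 ± 0.36), and Il12rb2 (1.72 ± 0.22), and 1 fell (6 and 3 adjusted over the list alone). Of 16 early TCR response genes 1 rose, the phosphatase gene Dusp2 (0.66 ± 0.11).

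Cell cycle genes did not pass singly, but only 2 of the 20 lay above 0 and the median was -0.57 (9.11e-06 by camera, adjusted p = 0.698 with an estimated correlation). Oxidative phosphorylation (6.04e-05), ribosomal protein (0.00183) and core TCR signalling genes (0.0347) pointed down as well, each with an adjusted p = 0.668 with an estimated correlation. Zbtb7b, which encodes the CD4 lineage factor ThPOK and stood in the list of CD4 cell markers, fell (-2.63 ± 0.45), and of 4 myeloid, 5 B cell and 2 tumor or stroma markers tested 0 passed. The count of 284 was 176 with an additive model, 418 with DESeq2 and 940 without the filter on low counts. It was 136 to 164 without any 1 of the B16 libraries, the MC38 KO isotype or the MC38 WT isotype library, and 765 and 731 without the MC38 KO ICB or the MC38 WT ICB library.

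**Figure D3:**
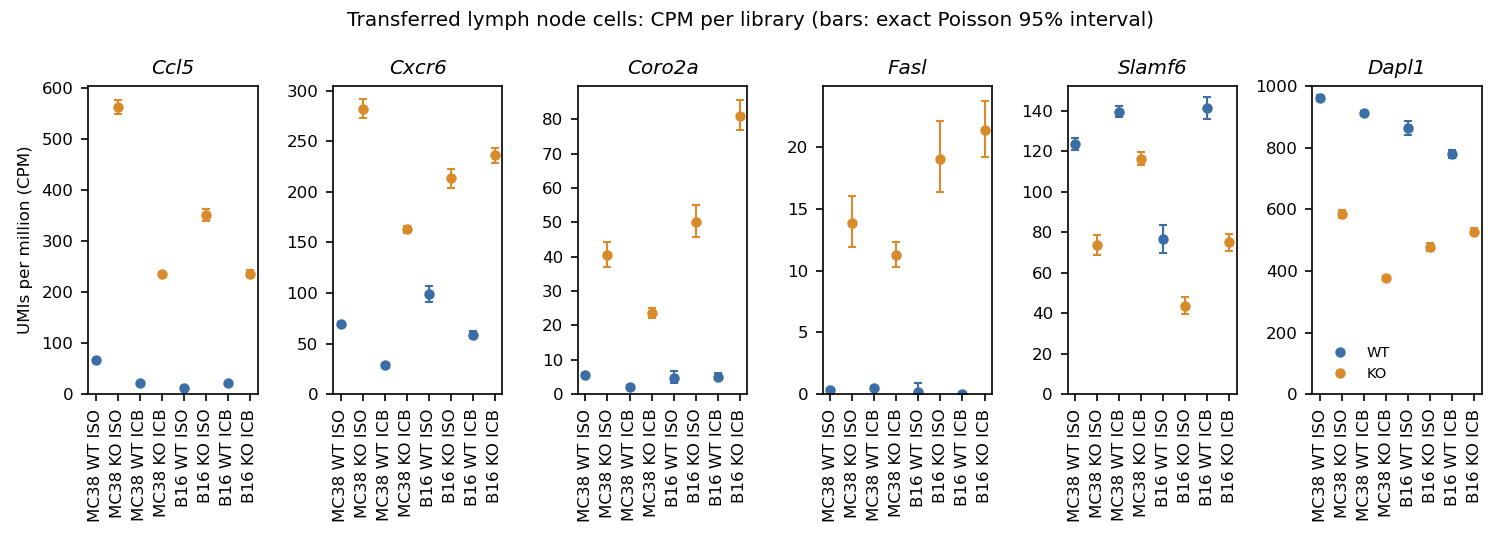
CPM (vertical, linear axes from 0) of Ccl5, Cxcr6, Coro2a, Fasl, Slamf6 and Dapl1 in the 8 lymph node libraries, with 1 point per library (blue WT, orange KO) and exact Poisson 95% intervals as error bars. Coro2a lay between 2.17 and 5.48 CPM in WT and between 23.5 and 81.1 CPM in KO libraries.

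Fitted per tumor model, the KO effect in the lymph node comprised 105 rises and 57 falls in MC38 and 77 rises and 68 falls in B16 among 11623 genes. Ccl5 (3.16 ± 0.30 in MC38 and 3.99 ± 0.32 in B16), Coro2a (3.09 ± 0.19 and 3.72 ± 0.22), Cxcr6 (2.21 ± 0.22 and 1.51 ± 0.22) and Sh3bp5 (1.61 ± 0.24 and 1.48 ± 0.24) rose in both models. Fam26f (2.19 ± 0.17) and Apol7e (1.53 ± 0.17) completed the largest rises in MC38, and the cytokine receptor genes Il18r1 (2.07 ± 0.22) and Il7r (1.32 ± 0.19) those in B16. In MC38 the largest falls were Tspan32 (-1.32 ± 0.18), Psen2 (-1.30 ± 0.17), Nsg2 (-1.28 ± 0.14), Mpp1 (-1.22 ± 0.17), Cd200 (-1.16 ± 0.18) and Izumo1r (-1.09 ± 0.15). In B16 they were Cd200 (-2.67 ± 0.21), Izumo1r (-2.62 ± 0.18), Wnt10a (-2.46 ± 0.31), Itm2a (-1.34 ± 0.15), Lag3 (-1.34 ± 0.19) and Cd44 (-1.33 ± 0.17). Of the list members, Prf1 (0.95 ± 0.15 and 0.87 ± 0.15) and Maf (2.01 ± 0.19 and 1.35 ± 0.23) rose in both models, Il2ra (2.62 ± 0.28), Entpd1 (1.97 ± 0.39) and Cx3cr1 (1.68 ± 0.32) in MC38, and Il18rap (2.27 ± 0.24) in B16. Cd4 rose at low levels (1.12 to 1.68 CPM in WT and 3.84 to 6.70 CPM in KO cells of MC38, 0.16 to 0.38 and 3.67 to 6.80 CPM in B16). Zbtb7b had 0.79 and 1.97 CPM in the WT and 0 UMIs in both KO libraries of B16. The MC38 count of 162 was 458 and 457 without the KO or WT ICB library of MC38. The B16 count of 145 was 15, 26, 74 and 82 without the WT ICB, KO ICB, KO isotype or WT isotype library of B16, and 405 to 447 without any 1 MC38 library.

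Of 16 checkpoint genes 2, Pdcd1 and Lag3, differed in their KO effect between the models. Pdcd1 (ENSMUSG00000026285; chromosome 1, 94038305 to 94052553) was at -0.01 ± 0.16 in MC38 (adjusted p = 0.986) and fell by 1.82 ± 0.22 log2 in B16 (adjusted p = 0.00218), and the difference of the effects was -1.80 ± 0.27 log2 (adjusted p = 0.0467, edgeR). In B16 its WT and KO values were 7.28 and 2.05 CPM under isotype and 12.9 and 3.88 CPM under ICB. In MC38 they were 16.1 and 14.2 CPM and 24.4 and 29.0 CPM. Lag3 (ENSMUSG00000030124; chromosome 6, 124904361 to 124911705) differed by -1.88 ± 0.25 log2 with the same adjusted p, with 9.50 and 2.91 CPM under isotype and 29.6 and 13.8 CPM under ICB in B16 (WT and KO), and 27.7 and 44.8 CPM and 63.1 and 88.9 CPM in MC38. In all 9 genes passed for this difference, 1 higher and 8 lower in B16. As a list, the 16 checkpoint genes had a median difference of -0.70 log2 with 2 falls, and 6 adjusted over the list alone (1.69e-09 by camera, adjusted p = 0.452 with an estimated correlation). The 16 Myc and ribosome biogenesis genes all had a lower KO effect in B16, with 5 passing adjusted over the list alone and 0 over all genes (1.36e-11, adjusted p = 0.668 with an estimated correlation). Type I interferon genes had a higher one (0.000146), and cytokine (0.00383), cell cycle (0.00383) and heat shock genes (0.0111) a lower one, each with an adjusted p = 0.761 with an estimated correlation. The B16 lymph node libraries also differed in the cluster led by Hspa1b and Hspa1a, which held 43.5% of WT and 48.4% of KO cells under isotype and 25.4% and 3.46% under ICB, and between 52.7% and 71.0% of their barcodes passed the quality limits. The count of 9 was 0 over all barcodes and over cells with a Cd8a or Cd8b1 UMI, 19 with DESeq2, and 0, 0, 3 and 3 without the KO ICB, WT ICB, KO isotype or WT isotype library of B16. It was 39 to 94 without any 1 MC38 library.

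ICB given 2 days before harvest was then compared with isotype in the lymph node, over 4 pairs. Cell cycle, checkpoint, interferon and effector genes lay above 0 with ICB as lists, but no single gene passed over all genes tested. All 20 cell cycle genes were above 0, with a median of 0.87 log2 (3.44e-14 by camera, adjusted p = 0.488 with an estimated correlation), and 4 rose adjusted over the list alone. Of 15 checkpoint genes 13 were above 0 and 7 rose adjusted over the list alone (5.81e-05, adjusted p = 0.252 with an estimated correlation). Pdcd1 was at 0.76 ± 0.12 log2, above 0 in 4 of 4 pairs (adjusted p = 0.110), Havcr2 at 2.21 ± 0.45 (adjusted p = 0.198), Cd274 at -0.05 (adjusted p = 0.966) and Tcf7 at 0.09 (adjusted p = 0.800). Of 20 type I interferon genes 18 were above 0, and 3 rose adjusted over the list alone (3.69e-05, adjusted p = 0.519 with an estimated correlation). Of 13 effector genes 11 were above 0, and 6 rose adjusted over the list alone (0.000201, adjusted p = 0.252 with an estimated correlation). Ribosomal protein genes pointed down (9.35e-11, adjusted p = 0.285 with an estimated correlation), with 10 of 96 above 0, and so did mitochondrial genes (0.00779, adjusted p = 0.588 with an estimated correlation). Camera also called glycolysis (0.00185), NK receptors (0.0156), the 4 myeloid markers tested (0.0163) and oxidative phosphorylation (0.0392) up, with a smallest adjusted p of 0.488 with an estimated correlation.

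Of 11127 genes 0 passed in edgeR, with 1383 at an unadjusted p under 0.05, and DESeq2 called 91 genes. Simulated changes of 1 log2 were recovered for 89.9% of genes. Without 1 library the count was 187 and 182 (B16 KO ICB or isotype left out), 20 and 9 (MC38 KO isotype or ICB), 2 and 2 (B16 WT ICB or isotype) and 0 (MC38 WT ICB or isotype). The proliferating class held 15.4% (14.5 to 16.3) and 29.8% (28.8 to 30.8) of MC38 WT cells (isotype and ICB), 4.38% (3.35 to 5.72) and 30.01% (28.5 to 31.5) of MC38 KO cells, and 0.774% to 3.76% of cells in B16. It left out an unnamed MC38 cluster led by the replication genes Cdc6 and Ccne2 (1612 cells, Mki67 at 249.2 CPM), which held 5.82% and 10.1% of WT and 2.84% and 10.8% of KO cells (isotype and ICB), so that the class is not the share of all cycling cells. The difference of the ICB effect between KO and WT cells gave 0 genes in edgeR (69 at an unadjusted p under 0.05, DESeq2 0 genes). Only 3.16% of simulated changes of 1 log2 and 67.0% of those of 2 log2 were recovered there. Without 1 library that count was 164 and 157 (B16 KO ICB or isotype left out), 38 and 14 (MC38 KO isotype or ICB), 2 (B16 WT isotype), 1 (MC38 WT isotype) and 0 (either WT ICB library). Type I interferon and heat shock genes had a lower ICB effect in KO cells (both 5.59e-11 by camera, adjusted p = 0.437 with an estimated correlation). NK receptors (0.000606), early TCR response (0.00157), Myc and ribosome biogenesis (0.00426), ribosomal protein (0.0113) and B cell marker genes (0.0113) were called lower as well and cell cycle genes higher (0.0113), with a smallest adjusted p of 0.437 with an estimated correlation. The cluster led by Hspa1b and Hspa1a held 3.46% of B16 KO ICB cells and 25.4% to 48.4% in the other B16 libraries.

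The tumor models themselves were compared over 4 pairs in each tissue, with the experiment and, in tumors, the harvest day confounded. In tumors 3685 genes were higher and 3550 lower in B16 than in MC38. All 20 cell cycle genes (Cdk1 1.57 ± 0.14) and all 16 Myc and ribosome biogenesis genes (Myc 1.49 ± 0.18) were higher in B16, together with Eno3 (2.66 ± 0.15), Csf2, which encodes GM-CSF (2.93 ± 0.13), and Tox, a regulator of exhaustion (1.79 ± 0.22). Of 16 cytotoxic genes 9 were lower and 0 higher in B16, with Gzmf at -3.93 ± 0.64 and Gzmd at -3.64 ± 0.96. Of 20 costimulation genes 17 were lower and 2 higher, with Icos at -2.45 ± 0.15 and Il12rb2 at -2.44 ± 0.16. The interferon-induced membrane proteins Ifitm1 (-5.40 ± 0.33) and Ifitm2 (-3.24 ± 0.28) were lower too, as were Lag3 (-1.56 ± 0.14), Pdcd1 (-0.66 ± 0.05), Havcr2 (-0.58 ± 0.10) and Cd274 (-0.64 ± 0.07). Tcf7 was higher by 0.38 ± 0.09 log2 (adjusted p = 0.0107). Markers of other cells moved with the model. The melanocyte genes Tyrp1 and Dct had 4.61 to 10.1 CPM and 6.94 to 19.0 CPM in B16 and at most 0.03 CPM in MC38. Of 16 myeloid markers 11 were higher and 2 lower in B16. All 4 haemoglobin genes were higher in B16, but Hba-a1 and Hba-a2 turned sign over all barcodes.

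In the lymph node 1738 genes were higher and 1871 lower in B16. Cell cycle genes were lower (18 of 20, Ccnb1 -4.12 ± 0.46), and so were Lgals3 (-7.79 ± 0.31), S100a6 (-5.93 ± 0.44), S100a4 (-5.63 ± 0.24), the integrin Itgb1 (-3.48 ± 0.18), Havcr2 (0.055 to 0.32 CPM in B16 and 1.81 to 16.2 CPM in MC38) and Pdcd1 (-1.82 ± 0.39, adjusted p = 0.0183). Ccr9, a gut homing receptor (2.97 ± 0.65), Igfbp4 (2.56 ± 0.42) and Bach2 (1.17 ± 0.21) were higher. All fold changes of these 2 comparisons passed in edgeR. The lymph node count of 3609 was 1547 without the MC38 WT ICB or the B16 WT ICB library, 1742 without MC38 WT isotype and 1822 without B16 WT isotype.

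Single libraries were compared without a test, as descriptions of these libraries. Checkpoint genes had a median ICB to isotype ratio above 0 in all 8 pairs of both tissues, between 0.22 log2 (B16 KO tumors) and 0.73 log2 (B16 WT lymph node). The naive and memory list had medians of -0.79 (MC38 WT), -0.41 (MC38 KO), -1.22 (B16 WT) and -0.68 log2 (B16 KO) in tumors. Cytotoxic genes had medians of 0.28, 0.36, 0.47 and 0.96 log2 in the same order. In B16 KO tumors Gzmd was at 1.66 CPM with isotype and 71.0 CPM with ICB, while in the WT libraries it was at 51.8 and 65.9 CPM. In MC38 WT tumors Areg was at 2.74 and 20.6 CPM, and in B16 WT tumors Spp1, which encodes osteopontin, was at 64.7 and 397 CPM. Between genotypes under ICB, Gzmf was at 4129 CPM in WT and 1188 CPM in KO cells of MC38 tumors. In the lymph node of MC38 mice, Ifitm1 was at 1.28 and 37.4 CPM in WT and 0.473 and 31.9 CPM in KO cells (isotype and ICB).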

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

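The tests on some host cells in B16, swapped or exchanged labels, free RNA, tags outside the deleted part, total UMIs, UMIs per cell and other splits of the samples were chosen only after the results were seen. The tests on host cells, on the clusters with Ccl5 and on class shares were written down before. Since each condition had 1 library, no group was large enough to be searched for libraries far from the others.

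A difference of effects between groups passed its own test in 10 cases. In tumors, the ICB effect on Ifi202b differed between KO and WT cells (20.16 ± 1.06 log2, adjusted p = 0.0242, edgeR, mean 1.27 CPM), a fitted value that rests on libraries without counts and is no bound. In the lymph node, the KO effect differed between B16 and MC38 for Pdcd1 (-1.80), Lag3 (-1.88), Myb (-1.77), Fam26f (-1.64), Izumo1r (-1.54), Cd83 (-1.49) and Gm21887 (-2.01), each with an adjusted p of 0.0467 (edgeR) and in 2 of 2 pairs. The same adjusted p held for Gm16867 (-8.34, mean 0.799 CPM) and Mgarp (6.49, mean 0.841 CPM), which lie at few counts. Fam26f rose in MC38 from 9.56 to 38.4 CPM under isotype, and was at 26.3 and 34.8 CPM in B16. Myb fell in B16 from 20.3 to 4.64 CPM under isotype and from 44.0 to 12.2 CPM under ICB, and was at 18.1 and 13.6 CPM and at 21.8 and 22.01 CPM in MC38. The tumor model was confounded with the experiment, so that the model and the experiment cannot be told apart for these genes. All 9 of these lymph node calls were absent when all barcodes were summed.

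A signal outside the main measurement was EGFP, with 263 UMIs over the libraries labelled KO and 0 over the WT libraries. It was found in 8 of 8 KO libraries (0.286 to 2.53 CPM), while 3 counts would have been 0.0265 to 0.402 CPM in the WT libraries.

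The first pattern weighed is that Tcf7 was not lower in the libraries labelled KO. If EGFP came with one genotype, some libraries swapped between the genotypes would place it in WT libraries, but it was seen in 8 KO libraries and 0 WT libraries. Its origin is not given, so an exchange of all the genotype labels stays open. Tcf7 was higher in the KO library in 5 of 8 pairs, and thus went one way under neither set of labels. Free RNA of wild-type cells would leave KO cells with less Tcf7 than WT cells, but the lymph node change was 0.304 log2 above 0, which argues against free RNA as the whole cause if the labels hold. Counted tags outside the deleted part of the gene could give this result. That stays open, since 0 matrices give the position of tags within Tcf7.

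The second pattern weighed is the rise of 182 genes in KO lymph node cells. Host cells sorted with the transferred cells would carry other receptor beta chains and so lower Trbv12-1 in the clusters with Ccl5 among their 20 leading genes (1 cluster in MC38 and 3 in B16). If they made up most of these clusters and all OT-I cells held the same level, its ratio to the other cells would be under 0.5. The ratio was 1.298 (95% interval 1.217 to 1.384) over the 4 KO libraries. MC38 carried that value, with 1.824 (1.535 to 2.167) and 1.849 (1.695 to 2.016) under isotype and ICB. In B16 it was 0.715 (0.57 to 0.895) and 0.903 (0.768 to 1.061). The MC38 values, far above 1, leave open that the level differs between OT-I cells of different clusters. The bound of 0.5 thus cannot exclude that host cells made up most of these clusters. In the B16 WT libraries Trbv12-1 was at 23.4 CPM in these clusters and 46.3 CPM in the other cells under isotype. Under ICB the WT values were 29.7 and 38.6 CPM. A lower level in these clusters was thus not particular to the KO libraries of B16. Host cells in B16 thus stay open, and 1 of the 3 clusters there, with 56 cells, was led by Tcrg-C4 with Trdc among its leading genes, which is not expected of OT-I cells. EGFP pointed both ways in B16 KO cells, at few counts. Under isotype it had 1 UMI in these clusters and 10 in the other cells (0.304 and 1.669 CPM). Under ICB it had 30 and 8 UMIs (2.674 and 1.523 CPM). Without those clusters the median KO to WT change of the 182 genes went from 0.969 to 0.842 log2, 86.9% of that over all cells (80.7% to 99.5% in the 4 pairs), which argues against a rise confined to them. The 20 distinct splits of the 8 libraries into 4 and 4 were too few for a share under 0.05, and 1 split, the real one, gave as many genes (284, highest other 280, a split that separates KO from WT in MC38 isotype and B16 ICB and is the genotype comparison over those 2 of the 4 pairs). A change of T cell state that goes with the KO label is a hypothesis that stays open.

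The third pattern weighed is the set of 222 genes that changed with ICB in tumors. Shares of cell classes alone could have produced it. Within the named classes the median change was 58.6% of that over all cells, where more than 50% had been written down beforehand as evidence against this. That bound was too close, since the value was 50% to 65.9% in the 4 pairs and 27.2% in the naive/central-memory-like class, so the question stays open. In the exhausted-like, proliferating and interferon-response-like classes it was 61.7%, 58.6% and 59.3%, and 97.3%, 99.5% and 89.6% of the genes there went in the direction over all cells, against 74.3% in the naive/central-memory-like class. A difference in total UMIs would leave genes without a shared direction, or turn it, in the 2 pairs whose ICB library had no more UMIs in all. Of the 222 genes with the smallest p in a fit without the MC38 KO pair, 182 (82%) went the same way in that pair (47288337 UMIs with ICB and 66201630 with isotype), and 207 of 222 (93.2%) did so in the B16 KO pair (97028533 and 98392229 UMIs), chosen without it. This argues against total UMIs as the whole cause, though it rests on 2 pairs, the second of which was added after the value of the first was seen. A difference in UMIs per cell stays open, since the median per cell was higher with ICB in 4 of 4 pairs (7008 and 7353 in MC38 WT, 5893 and 7246.5 in MC38 KO, 4854 and 10267 in B16 WT, 6579 and 8463.5 in B16 KO, isotype and ICB), so that it cannot be told apart from the treatment. For the other comparisons, too, the 20 splits were too few for a share under 0.05: 1 split gave as many genes as the real one in tumor treatment (222, highest other 0), tumor genotype (2, highest other 1), tumor model in tumors (7235, highest other 0) and in the lymph node (3609, highest other 0). In lymph node treatment the real split gave 0 genes, so that 20 of 20 were as large, and the highest other gave 696, which points to a structure of the samples: it compares ISO with ICB in MC38 alone.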

How the results depend on the processing

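The removal of cells by doublet score, sums within classes, sums without the clusters with Ccl5 among their 20 leading genes, clustering without called genes and the fits of treatment per tumor model were chosen only after the results were seen, and the other alternatives were planned. Numbers are genes that passed, and where no reason is given the cause was not tested.

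In tumors, the 2 genotype genes became 204 with DESeq2's Wald test, 0 with its size factors, 1 with the additive model, 0 over all barcodes, 0 over cells with a Cd8a or Cd8b1 UMI, 53 without the filter and 0 without cells of high doublet score. Sums within classes gave 10 (exhausted-like), 38 (proliferating) and 118 (naive/central-memory-like). The 222 treatment genes became 835 (Wald test), 20 (all barcodes), 18 (Cd8a or Cd8b1), 440 (no filter), 46, 36, 13 and 0 within the exhausted-like, proliferating, naive/central-memory-like and interferon-response-like classes, 2 in MC38 and 0 in B16. The genotype effect in MC38 went from 0 to 71 (Wald test) and 7 (no filter), in B16 from 0 to 59, 5 and 1 (doublet score), its difference by tumor model from 0 to 18 and 6, and to 10 (exhausted-like) and 14 (proliferating) within classes, and that by treatment from 1 to 30, 13, 0 (additive), 0 (doublet score), and 0, 2, 6 and 0 within the exhausted-like, proliferating, naive/central-memory-like and interferon-response-like classes.

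In the lymph node, the 284 genotype genes became 176 (additive) and 940 (no filter), and 210 without the clusters with Ccl5 among their 20 leading genes, of which 159 were shared. Treatment went from 0 to 91 (Wald test), 183 (no filter), 1 (doublet score), 546 (MC38 alone) and 1 (B16 alone). Genotype in MC38 went from 162 to 455 and in B16 from 145 to 480 without the filter. The 9 genes of the difference by tumor model became 0 (all barcodes), 0 (Cd8a or Cd8b1), 19 (Wald test), 90 (no filter) and 15 (doublet score).

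With each library left out in turn, the ranges in tumors were 0 to 7 (genotype), 30 to 174 (treatment), 0 to 62 (genotype in MC38), 1 to 47 (in B16), 0 to 19 (by tumor model), 0 to 327 (by treatment) and 5997 to 6417 (tumor model). In the lymph node they were 136 to 765, 0 to 187, 140 to 458, 15 to 447, 0 to 94, 0 to 164 and 1547 to 4339 in the same order. The partner of a left-out library is then alone in its block and adds nothing to the effect. Each of these fits thus leaves out a pair in effect, and leaving out either library of a pair is nearly the same check.

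Of 43 list calls in tumors and 32 in the lymph node, 0 and 0 held with an estimated correlation (smallest adjusted p 0.267 and 0.247, camera). The exhausted-like share was higher with ICB in 3 of 4 pairs, and in 4 at resolution 1.2. Class shares left their Wilson interval in 48 of 78 cases at resolution 1.2, 24 of 74 with another seed, 24 of 66 with at least 1000 genes, 26 of 70 without cells of high doublet score, 13 of 36 without called genes in the clustering and 1 of 78 with doublets kept. Between tumor models, called genes turned sign for Atf3 (1.41 over all barcodes, 1.18 over cells with a Cd8a or Cd8b1 UMI), Siglech (-1.28 and -1.34), Hba-a1 (-0.91) and Hba-a2 (-0.92, all barcodes) in tumors, and Cd74 (0.45, all barcodes) in the lymph node. Of 3153 values of called named genes under the alternatives, 2616 kept their call, 529 lost it (384 with 1 library left out), 7 turned sign and 1 had no adjusted p, while 19 uncalled ones gained a call. Scalings moved the median of all genes by between -0.0196 and 0.0193 log2. Of 370 single-library medians, 7, 36 and 28 turned sign with 5 counts added, TMM scaling and all barcodes, with largest moves of 1.54, 0.096 and 5.31 log2. At this depth 3.16% of simulated changes of 1 log2 were recovered for lymph node genotype by treatment.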

Other observations

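The treatment effects per tumor model, the tests within cell classes, the overlap test and the test of genes near Tcf7 were chosen only after the results were seen. Fitted per tumor model, 332 genes rose and 214 fell among 11623 in lymph node T cells of MC38 mice 2 days after ICB (edgeR). This fit was added after the split that compares ISO with ICB in MC38 alone had given the most genes (696). These calls are thus no independent evidence. They rest on 2 pairs and were not rerun with DESeq2, all barcodes or libraries left out. No test of the lists was run there. Of 20 naive and memory genes 5 fell, including Lef1 (-0.74), Bach2 (-0.81) and Id3 (-0.85). Of 16 checkpoint genes tested 4 rose, Ctla4 (1.26), Lag3 (1.03), Pdcd1 (0.74) and Havcr2 (2.37), and Tox fell (-0.56). Of the 21 type I interferon genes 5 rose, including Rsad2 (1.57) and Mx1 (1.45), of 20 cell cycle genes 3, including Cdk1 (1.30), and of 13 effector genes 3, including Bhlhe40 (1.91) and Prdm1. Of 11 cytokine and chemokine genes 2 fell, including Ccl5 (-1.47), and 0 rose. Of 16 homing and residency genes Cxcr3 rose, and Cxcr6 (-1.09) and Ccr9 (-2.69) fell. Of 13 cytotoxic genes 1 rose and 1 fell, and of 20 costimulation and cytokine receptor genes 3 rose and 1 fell. Of the markers of other cells, Cd74 rose (1.13) and Ighd (-1.27), Cd40lg (-1.39) and Eomes (-0.97) fell. Eomes is also among the 5 naive and memory genes that fell.

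In B16 lymph nodes 1 gene passed, Lag3 (1.81 ± 0.20, adjusted p = 0.0215, edgeR), with 396 at an unadjusted p under 0.05. The difference between the models gave 0 genes in edgeR (1062 at an unadjusted p under 0.05, not run with DESeq2), so that the ICB effect was not shown to differ between them. In tumors 2 genes passed in MC38, including Rgs2, 0 in B16 (1502 at an unadjusted p under 0.05) and 0 for the difference (687).

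Within the naive/central-memory-like class of tumor T cells, 89 genes rose and 29 fell in KO cells among 9531 (edgeR), against 1 and 1 over all T cells. The rises included Fasl (1.70), Entpd1 (1.43), Serpinb9 (1.30), Cxcr6 (1.26) and Ccl5 (0.86), and also Ccr7 (0.48) and Satb1 (0.31) of the naive and memory list, while the falls included Gzme (-1.91), Gzmf (-1.57), Cd200 (-1.20), Actn1 (-0.85) and Myb (-0.69). A candidate explanation is that the genotype labelled KO raises the same genes in naive-like tumor cells and in transferred lymph node cells. Of the genes tested in both, 86 were higher in the class and 170 in the lymph node, and 34 in both where 1.55 were expected (Fisher's exact test, adjusted p = 1.5e-37), among them Fasl, Prf1, Cxcr6 and Il12rb2. Of the lower genes, 27 and 75, there were 6 in both (expected 0.21, adjusted p = 5.35e-08, Fisher's exact test). This is consistent with a shared change, but genes are not independent and the class was defined on the same cells. In MC38 the class joined a Dapl1 and a Klra7 cluster, which held 4.30% and 3.66% of T cells in the WT ICB library while the Klra7 cluster held most of the class in the other 3, so a change in that mix may contribute and was not tested.

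Of 159 genes within 10 Mb of Tcf7 7 (4.4%) were called in the lymph node, against 256 of 10190 (2.51%) on other chromosomes (Fisher's exact p = 0.127), with the rest of chromosome 11 left out, and in tumors 0 of 186 against 2 of 12325 (Fisher's exact p = 1). Of the 7, 6 rose and 1 fell. The positions of 2 of them overlap that of Tcf7, Gm26551 (1.46 ± 0.14 log2, adjusted p = 0.000540) and A630014C17Rik (1.04 ± 0.24 log2, adjusted p = 0.0456, edgeR), both named after their values were seen. How this relates to the Tcf7 count was not tested. DNA carried along with the altered allele was thus neither shown nor excluded.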
